A study of Homo sapiens with 8 samples.

How the data were processed

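IMR90 cells, which are human fetal lung fibroblasts, were measured in 8 libraries from 2 experiments. The RNA-seq experiment held 1 control library and 1 library with knockdown of ADAR1 (gene ADAR), an enzyme that edits adenosine in double-stranded RNA. The RNA immunoprecipitation experiment held cells with shControl, shADAR1 or shHuR, and each of these 3 lines gave 1 precipitate with an antibody against HuR and 1 input library. HuR (gene ELAVL1) is a protein that binds AU-rich elements, mostly in the 3' untranslated regions of mRNAs. Per the labels' protocols, libraries of the RNA-seq experiment were made with the KAPA RNA HyperPrep kit from total RNA, and precipitates were made with the Magna RIP kit. Groups were taken from the sample titles, and each file column was matched to a sample by its header.

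The deposited expected counts are gene-level estimates from RSEM 1.2.3 per the submitters' processing notes, which name hg19 for both experiments and also GRCh37 for the precipitation experiment. These deposited values are whole numbers, so they entered the count models as they were. The RNA-seq file also holds deposited FPKM values (fragments scaled by transcript length and library size), which served only in an alternative fit. DESeq2 is named for the RNA-seq in the submitters' processing notes, but no fold changes or p-values of theirs were in the files. The aligner, the annotation release, any filter before deposition and the strand setting of the counting were not given in the sources used here. Antisense genes therefore could not be separated from their partners on the opposite strand. No coordinates are given, because the gene tables at hand follow a later genome build.

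Both files listed the same 57736 Ensembl gene IDs, with genes at 0 kept. Symbols came from a gene table for 39501 IDs and from GENCODE 29 for 504 more, so that 69.3% had a symbol and 17731 had none. A further 1154 IDs shared a symbol with a more abundant ID and were not reported under it. Exon overlap with other genes was computed for the named genes, and readthrough genes, members of multigene families and genes with more than 50% of their exon length shared are reported as uncertain or as overlapping. That limit was set after the overlaps were seen, and genes below it carry no mark, such as ASNS (44.6%), DDIT4 (41.2%), SAPCD2 (22.9%), GALNT12 (21.1%), INMT (16.65%) and DENND6B (15.7%).

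Total counts were 39172819 in the RNA-seq control and 50711218 in the RNA-seq knockdown. The precipitates held 38953671 (shControl), 44578878 (shADAR1) and 29233961 (shHuR) counts, and the inputs held 36717888, 28390935 and 34863880 in the same order. Beta-actin (ACTB) took 7.69%, 7.48% and 5.71% of the precipitates' counts, against 1.01%, 1.13% and 0.99% of the inputs'. A pair of IDs without a symbol took 13.6%, 12.8% and 10.5% of the inputs' counts, against 0.17%, 0.44% and 2.09% of the precipitates' and 4.31% and 3.49% in the RNA-seq.

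Each group held 1 library. Differences between a pair of libraries were therefore computed as the log2 ratio of counts scaled by TMM (trimmed mean of M values), with the exact conditional binomial interval at 95%, which covers counting error only. A prior count of 2 was added for values across genes, in list medians and in calls. Where a library held 0 counts, the fold was computed against a floor of 3 counts in that library and given as "at least"; intervals are given for genes with 1 to 3 counts. A gene was called higher or lower when it differed by at least 2-fold and had at least 50 counts in one of the libraries. Enrichment was the ratio of precipitate to input in the same line. Genes enriched at least 2-fold in shControl were called HuR-dependent when their enrichment was at least 1.5-fold higher than in shHuR. Differences in enrichment between lines were called at 1.5-fold among genes whose mean log2 enrichment over the compared lines was at least 1, so that the choice favoured neither line.

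Tests were possible where libraries of both experiments or all lines were combined. ADAR1 knockdown was tested over the RNA-seq pair and the shControl and shADAR1 inputs (4 libraries, 1 residual degree of freedom) with the experiment as block. HuR precipitate against input was tested over the 3 lines (6 libraries, 2 residual degrees of freedom) with the cell line as block. The pairing comes from the labels, since both libraries of a block have the same experiment or the same line. Both used the quasi-likelihood test of edgeR 4.0.16 with its filter on low counts, TMM and Benjamini-Hochberg adjustment at 0.05. The p-values measure only the spread between these libraries, which hold 1 culture per line or condition. The fitted dispersion was 0.15 for the knockdown test and 0.1 for the precipitation test.

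The tests were tried on simulated counts with 200 changed genes. At a dispersion of 0.02, 98 of 100 genes changed 4-fold were found in the knockdown design and 96 of 100 in the precipitation design. At the dispersion of the real knockdown libraries, 0 of 100 genes changed 2-fold and 6 of 100 changed 4-fold were found among 16005 genes, with 0 false calls. At the dispersion of the real precipitation libraries, 7 of 100 genes changed 2-fold and 86 of 100 changed 4-fold were found among 15932 genes, with 2 false calls. On simulated pairs of libraries with counting error alone (Poisson counts), the counting interval covered 95.3% of the true ratios over 4000 genes. Spread between libraries was not simulated there, so this checks the computation and not the cover in real libraries.

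Gene lists were fixed before the data were examined: targets and senescence markers, cell cycle, senescence-associated secretory, p53 targets, interferon-stimulated, sirtuins, integrated stress response, autophagy and lysosome, extracellular matrix and contractile, cholesterol synthesis, reported HuR targets, AU-rich-element-binding proteins, RNA editing enzymes, cytosolic ribosomal proteins, replication histones, mitochondrially encoded genes, and markers of epithelial, endothelial and leukocyte cells. The mitochondrially encoded list matched 0 symbols and gave no value. A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. The samples, comparisons, alternatives and the rule for named genes were fixed at the same time.

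The rule named ADAR, ELAVL1, SIRT1, CDKN2A, CDKN1A and LMNB1 everywhere. For ADAR1 knockdown it named the 10 highest and 10 lowest genes by mean log2 ratio among those called in the same direction in both experiments, and for the shHuR input the 10 highest and 10 lowest. For the precipitates it named the 10 most enriched HuR-dependent genes in shControl, and the 10 highest and 10 lowest differences in each comparison between lines. Up to 4 members of each list with the largest log2 ratio could be named as well. Genes without a symbol, with clone-based names or called pseudogenes were left out, and fewer may be printed from the top of each ranking. The genes past the threshold in the knockdown test that lie outside this rule were named after their values were seen.

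Alternatives were DESeq2 1.42.0 in place of edgeR, other scalings (DESeq2 size factors and total counts), other minimum counts (20 and 200), no filter on low counts, fits without the block, fits that left out one line, log2(FPKM + 1) for the RNA-seq, and a choice of enriched genes in shControl alone. Rescaled enrichments and the removal of trends over GC content and transcript length were added after the data were seen. Comparisons that share the shControl libraries were set against 20 simulated draws of unchanged libraries with the same control. The simulated draws kept the scaling factors of the real libraries. Computations ran in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. RNA editing was not analysed here, since counts per gene do not show it.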

Results

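RNA levels in IMR90 fibroblasts were compared between a control and an ADAR1 knockdown library of an RNA-seq experiment, and between input libraries of shControl, shADAR1 and shHuR cells. Recovery with the antibody against HuR was read from the precipitate of each of these 3 lines against its own input. The experiment held no mock precipitate, so enrichment alone does not separate binding to HuR from unspecific recovery. The question of the series, from its title, is how loss of ADAR1 bears on p16 (CDKN2A) and senescence. Each group held 1 library, so the differences between a pair of libraries have no replicate check, and their intervals, given at 95%, cover counting error only.

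The targeted genes were lower in the libraries labelled with their knockdown. ADAR (ENSG00000160710) was 7.01-fold lower in the RNA-seq knockdown (1445 against 7732 counts; log2 ratio -2.81, interval -2.89 to -2.73) and 2.96-fold lower in the shADAR1 input (3142 against 12890 counts; -1.56, -1.62 to -1.51). ELAVL1 (ENSG00000066044) was 6.65-fold lower in the shHuR input (674 against 4806 counts; -2.73, -2.85 to -2.62). ADAR had a log2 ratio of -0.35 in the shHuR input. ELAVL1 stood at -0.07 (-0.16 to 0.01) in the RNA-seq knockdown, or 0.12 with trends over GC content and transcript length removed. In the shADAR1 input it stood at 0.03 (-0.03 to 0.10), or -0.07 with scaling by total counts and -0.03 with those trends removed.

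In the RNA-seq experiment, SIRT1 (ENSG00000096717), a NAD-dependent deacetylase, was 2.44-fold lower after ADAR1 knockdown (844 against 1569 counts; log2 ratio -1.28, interval -1.41 to -1.16). CDKN2A (ENSG00000147889), which encodes the inhibitors p16 and ARF, was 1.60-fold higher (381 against 182 counts; 0.68, 0.42 to 0.94), short of the 2-fold limit. CDKN1A (ENSG00000124762), the inhibitor p21, was 2.16-fold lower (-1.11, -1.14 to -1.07). LMNB1 (ENSG00000113368), a lamin of the nuclear envelope, was 1.45-fold higher (0.54, 0.48 to 0.59). With trends over GC content and transcript length removed, the RNA-seq ratios were -0.83 for SIRT1, under 2-fold, and 0.15 for CDKN2A. Of 13235 genes with enough counts, 1100 were higher and 1020 lower, and 619 were lower once those trends were removed.

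Secreted factors of senescent cells were higher in the RNA-seq knockdown, with a median log2 ratio of 1.17 over 16 members (percentile 100 among random lists), 8 higher and 2 lower. Among them the growth factor AREG was 78.6-fold higher, the metalloproteases MMP10 (71.8-fold, from 2 control counts; log2 interval 4.29 to 9.22) and MMP3 (11.9-fold) were higher, and so was the decoy receptor TNFRSF11B (7.01-fold). Replication histones had a median of 1.03 over 32 members (percentile 100), 20 higher and 0 lower, with H2BC26 at 5.19-fold and H1-1 at 4.93-fold. Cell cycle genes had a median of 0.38 over 30 members (percentile 99.97); MYBL2 (2.31-fold) and E2F1 (2.16-fold), both transcription factors of the cell cycle, were the 2 called higher and 0 were lower. Cytosolic ribosomal proteins had a median of 0.55 over 82 members (percentile 100), 10 higher and 2 lower, from RPL41 at 4.07-fold higher to RPL22L1 at 2.34-fold lower. Autophagy and lysosome genes had a median of 0.68 over 17 members (percentile 100), with 4 higher and 0 lower: GABARAPL1 (3.41-fold), NPC1 (2.66-fold), ULK1 (2.60-fold) and CTSD (2.35-fold; uncertain, since it overlaps another gene).

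Of 14 genes of the integrated stress response, 3 were higher and 2 lower after knockdown in the RNA-seq (median 0.44, percentile 99.1), among them the cystine transporter SLC7A11 (10.2-fold higher) and DDIT4 (2.60-fold lower). Matrix and contractile genes had 4 members higher and 1 lower of 20 (median 0.12, percentile 86.6), including CCN2 (3.42-fold) and the collagen COL1A1 (3.10-fold). For p53 targets the split was 2 higher and 3 lower of 20 (median -0.25, percentile 10.96), with GDF15 3.14-fold higher and TP53INP1 2.82-fold lower. Of 20 interferon-stimulated genes, 4 were higher and 2 lower (median 0.06, percentile 57.7), with IFITM1 2.65-fold higher and the RNA sensor RIGI 2.56-fold lower. Reported HuR targets gave 3 higher and 4 lower of 28 (median 0.17, percentile 89.8), with the prostaglandin synthase PTGS2 6.62-fold higher and HIF1A 2.87-fold lower. Cholesterol synthesis had 0 of 12 members called (median -0.14), sirtuins 1 lower of 6 (median -0.29), and AU-rich-element-binding proteins 1 lower of 14 (median -0.10). Of the other cell types' markers, the endothelial receptor KDR was 5.55-fold higher, while epithelial CLDN4 and EPCAM and leukocyte CD68, which overlaps other genes and is uncertain, stayed under 2-fold.

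In the shADAR1 input, most interferon-stimulated genes and senescence-associated secretory genes were above the shControl input. The chemokine CXCL1 was 283-fold higher (log2 ratio 8.14, interval 7.44 to 8.95) and CXCL8 221-fold higher (7.79, 7.23 to 8.40). The antiviral synthetases OAS2 (111-fold, 481 against 6 counts), OASL (at least 50.9-fold) and OAS1 (at least 30.5-fold) and the protein IFI6 (9.11-fold) were higher too. SIRT1 was 1.63-fold lower (-0.70, -0.87 to -0.55), LMNB1 2.45-fold lower (-1.29, -1.44 to -1.15), CDKN2A 1.18-fold higher (0.24, 0.11 to 0.36), and CDKN1A stood at -0.15 (-0.18 to -0.13). With the GC and length trends removed, CDKN2A stood at 0.96 and CDKN1A turned to 0.15. Of 13192 genes, 1179 were higher and 1395 lower, and with those trends removed 1259 were higher and 954 lower.

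Interferon-stimulated genes had a median log2 ratio of 1.73 over 27 members in the shADAR1 input (percentile 100; the same with members at 0 counts placed at their bound), 20 higher and 1 lower. Senescence-associated secretory genes had a median of 2.08 over 19 members (percentile 100), 14 higher and 0 lower, with MMP3 at 133-fold (2 control counts; log2 interval 5.18 to 10.11). Matrix and contractile genes were split into 8 higher and 2 lower of 19 (median 0.82, percentile 99.96), with LUM 4.11-fold and DCN 3.27-fold higher and BGN, like these a small proteoglycan, 3.51-fold lower. Cell cycle genes had a median of -1.19 over 30 members (percentile 0), with 18 lower and 0 higher, among them the centromere histone CENPA (4.88-fold lower) and the transcription factor FOXM1 (3.79-fold lower). Replication histones (median -1.15 over 30, 18 lower and 0 higher) and ribosomal proteins (median -0.81 over 82, 20 lower and 0 higher) lay at percentile 0 as well, with H3C13 5.76-fold, RPL22L1 3.53-fold and RPS2 2.69-fold lower. Cholesterol synthesis had 8 of 12 members lower and 0 higher (median -1.07, percentile 0), such as INSIG1 (10.2-fold lower), a regulator of that pathway.

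Reported HuR targets in the shADAR1 input gave 8 higher and 4 lower of 29 (median 0.31, percentile 94.3), with PTGS2 22.3-fold and FOS 6.86-fold higher and the survival factor BCL2 3.55-fold lower. Of 14 stress response genes 2 were higher and 2 lower (median -0.20), with SLC7A11 5.98-fold higher and the pseudokinase TRIB3 3.17-fold lower. GABARAPL1 (4.18-fold higher) was the 1 member called of 18 autophagy and lysosome genes (median 0.31). p53 targets had 1 lower and 0 higher of 20 (median -0.02), sirtuins 0 of 6 called (median -0.33), and AU-rich-element-binding proteins 0 of 14 (median -0.12). Among other cell types' markers, the monocyte receptor CD14 had a log2 ratio of 7.72 (from 1 control count; 5.22 to 13.03), the endothelial TEK was 4.44-fold higher while VWF (2.02-fold) and ROBO4 (2.52-fold), of the same list, were lower, with ROBO4 called, and CLDN4 stood at -1.37.

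Both ADAR1 knockdown experiments together had 174 genes higher and 134 lower in the same direction, of 12250 genes with enough counts in both, against 57.8 and 88.8 for independent lists of these sizes. Another 156 genes were higher in the RNA-seq knockdown and lower in the shADAR1 input (70.3 for independent lists), and 112 the reverse (73.1). Across these genes, which are not independent replicates, the correlation of log2 ratios was 0.06 (Pearson) and -0.07 (Spearman), and 45.5% had the same sign. Higher in both, with folds in RNA-seq and input, were ANKRD1, a muscle ankyrin-repeat protein (22.2-fold and 85.4-fold), the lectin COLEC10 (136-fold and 17.8-fold), the chloride channel CFTR (97.7-fold, from 1 control count, log2 interval 4.11 to 11.93; and 47.4-fold), MMP3, AREG (78.6-fold and 9.42-fold), CXCL8 (5.59-fold and 221-fold) and SORBS2 (14.3-fold and at least 52.3-fold). The flippase gene ATP8B4 was 5.34-fold higher in the RNA-seq and had 343 counts against 1 in the inputs (log2 interval 6.41 to 14.20). AMIGO3 (at least 80.9-fold and at least 115-fold) is uncertain, since its exons overlap another gene, and RIPOR3-AS1 (43.5-fold, from 3 control counts, log2 interval 3.87 to 7.74; and 115-fold) is an antisense gene. Lower in both were SLC7A14 (11.1-fold and 12.9-fold), SCD, the stearoyl-CoA desaturase (3.21-fold and 23.0-fold), the keratin KRT19 (4.59-fold and 13.5-fold), the potassium channel KCNK2 (2.39-fold and 32.3-fold), KLHL13 (3.43-fold and 46.0-fold), GALNT12 (7.18-fold and 17.7-fold), PPL (4.35-fold and 27.2-fold), MAB21L2, which overlaps another gene (4.26-fold and 21.8-fold), and PAK3 (5.24-fold and 57.7-fold, from 1 count; log2 interval -11.17 to -3.33); GOLGA6L9, of a multigene family, is uncertain.

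Over both experiments, 13 genes rose and 2 fell with ADAR1 knockdown in the edgeR test of 15994 genes, while 761 had an unadjusted p under 0.05. ANKRD1 rose by 5.36 (SE 0.65) on the log2 scale (edgeR adjusted p 0.0215), the melanosome enzyme TYRP1 by 8.36 (SE 1.09; adjusted p 0.0254 in edgeR), the integrin ITGA8 by 4.10 and the protease inhibitor A2M by 4.06 (edgeR adjusted p 0.0221 for both). The transporter SLC16A6 (4.36, SE 0.49), COLEC10 (5.44), BMP2, a bone morphogenetic protein (3.25), MAP2, a microtubule protein (3.88), CFTR (5.84), VWA5A (3.00) and the methyltransferase INMT (3.26) rose as well, as did RIPOR3-AS1 and AMIGO3. SLC7A14 (-3.58, SE 0.53; edgeR adjusted p 0.0477) and GOLGA6L9 fell. ADAR itself was at -2.19 (SE 0.50; edgeR adjusted p 0.275), SIRT1 at -0.99 (SE 0.43; edgeR adjusted p 0.991), CDKN2A at 0.45 (SE 0.44), LMNB1 at -0.37 (SE 0.53) and CDKN1A at -0.63 (SE 0.48). With DESeq2, 92 genes rose and 24 fell; without the experiment as block, edgeR called 0 in either direction, with 85 at an unadjusted p under 0.05.

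No list had a member past the edgeR threshold over all genes in the knockdown test. Adjusted over the list alone, 9 of 19 senescence-associated secretory genes rose, 3 of 29 reported HuR targets, 1 each of the stress response (SLC7A11), autophagy and lysosome (GABARAPL1) and matrix (CCN2) lists, and 2 of 4 endothelial markers (KDR and TEK). KDR had 0 counts in the shControl input and 2 in the shADAR1 input, so its rise rests on the RNA-seq pair (538 against 74 counts). ADAR fell when adjusted over the list alone, among the 6 targets and senescence markers and among the 2 RNA editing enzymes. For interferon-stimulated genes, 0 of 25 passed and 3 had an unadjusted p under 0.05, and for cell cycle genes both counts were 0 of 30. The ribosomal protein list had 0 of 82 past the list's own adjustment and 1 at an unadjusted p under 0.05.

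**Figure D1:**
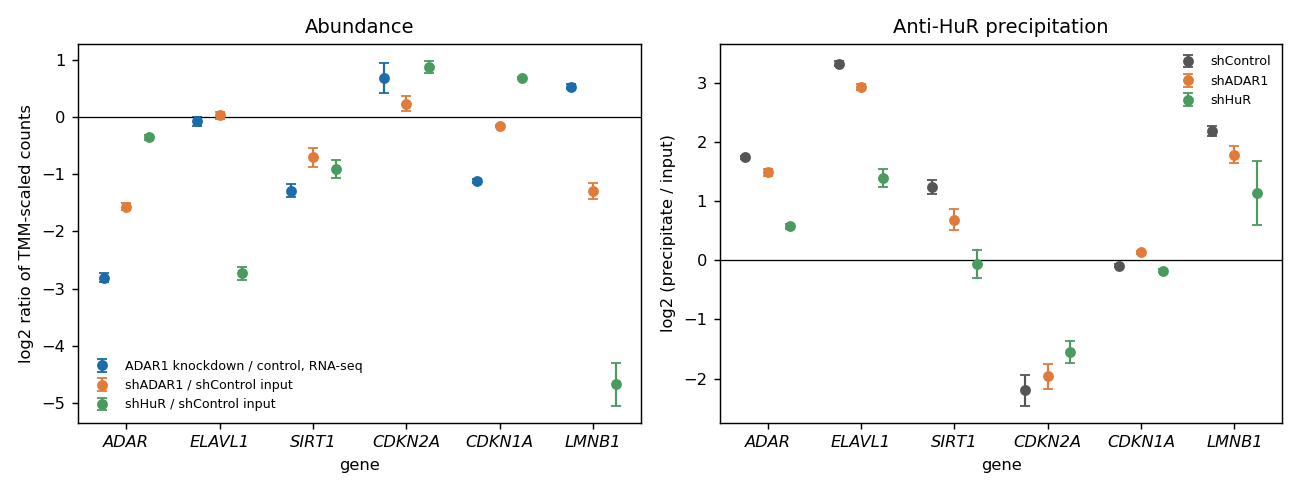
Left, log2 ratios of the targeted genes and senescence markers in the RNA-seq knockdown, the shADAR1 input and the shHuR input against their controls; right, their log2 ratio of HuR precipitate to input in shControl, shADAR1 and shHuR cells (1 library or pair per point, bars for the counting interval). ADAR is at -2.81 and -1.56 in the ADAR1 knockdowns and ELAVL1 at -2.73 in the shHuR input, and SIRT1 is at 1.24, 0.69 (-0.17 with scaling by total counts) and -0.06 in the precipitates.

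In the shHuR input, cell cycle genes were lower and secretory genes higher than in the shControl input. LMNB1 was 25.3-fold lower (63 against 1709 counts; log2 ratio -4.66, interval -5.05 to -4.30), CENPA 75.7-fold, MYBL2 52.8-fold and the proliferation marker MKI67 25.1-fold lower. CXCL8 was 1006-fold higher (24392 against 26 counts; 9.97, 9.42 to 10.59), CXCL1 278-fold and ANKRD1 180-fold higher. CDKN2A was 1.83-fold higher (0.87, 0.77 to 0.98), CDKN1A 1.61-fold higher (0.68, 0.66 to 0.70) and SIRT1 1.87-fold lower (-0.90, -1.06 to -0.75). With the GC and length trends removed, CDKN2A (1.502) and SIRT1 (-1.065) passed 2-fold, and CDKN1A stood at 0.95. Of 13390 genes, 1610 were higher and 2123 lower.

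Other genes far higher in the shHuR input were PDK4 (at least 472-fold), a kinase that restrains pyruvate oxidation, the transporter SLCO2B1 (at least 255-fold), TYRP1 (at least 217-fold), ENPP4 (at least 173-fold), TMEM178B (294-fold), and EHF and MMP3 (1191 and 1186 counts against 2; log2 intervals 7.46 to 12.37 and 7.46 to 12.36). Far lower were the muscle filament DES (83.3-fold), the collagen COL15A1 (81.7-fold), SAPCD2 (80.7-fold), TROAP (122-fold), BAALC (72.3-fold), the sodium channel SCN7A (at least 54.7-fold), PPL (at least 46.9-fold) and KRT19 (2 against 412 counts; -10.64 to -5.72). The readthrough genes DNAJC25-GNG10 and TGIF2-RAB5IF are uncertain.

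Cell cycle genes in the shHuR input had a median of -3.62 over 30 members (percentile 0), 29 lower and 0 higher. Replication histones had a median of -3.19 over 30 (percentile 0; 25 lower, 0 higher), with H1-3 52.3-fold lower, and ribosomal proteins -0.97 over 82 (percentile 0; 35 lower, 0 higher), with RPLP0 3.22-fold lower. All 23 senescence-associated secretory genes had ratios above 0 (median 3.09, also with members at 0 placed at their bound; percentile 100), and 19 were called higher, among them CCL20 (at least 81.9-fold). Cholesterol synthesis had 6 lower and 0 higher of 12 (median -1.06, percentile 0.02), with INSIG1 44.8-fold lower. The stress response had 6 lower and 1 higher of 14 (median -0.87, percentile 0.06): PHGDH, an enzyme of serine synthesis, was 17.2-fold and ASNS, the asparagine synthetase, 3.22-fold lower, while SLC7A11 was 6.01-fold higher. Autophagy and lysosome genes had 6 higher and 1 lower of 18 (median 0.78, percentile 99.93), with GABARAPL1 7.08-fold higher and TFEB 3.04-fold lower.

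Reported HuR targets in the shHuR input had 7 higher and 6 lower of 29 (median 0.14, percentile 64.3), from PTGS2 at 46.9-fold higher to BCL2 at 10.99-fold and CCNA2 at 7.91-fold lower. AU-rich-element-binding proteins had 4 lower and 1 higher of 14 (median -0.41, percentile 1.65), with ZFP36L2 4.44-fold and HNRNPD 2.61-fold lower and ZFP36L1 2.22-fold higher. Matrix genes had 7 higher and 3 lower of 19 (median 0.34), with LUM 5.31-fold higher and BGN 8.04-fold lower. Interferon-stimulated genes had 5 higher and 6 lower of 22 (median -0.28, percentile 23.98), with CXCL10 10.98-fold higher and OAS3 7.08-fold lower. p53 targets had 3 higher and 1 lower of 20, and sirtuins 0 of 6 called (median -0.26). The editing enzyme ADARB1 was 2.13-fold lower, and the endothelial markers had 1 higher and 2 lower of 3.

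The shADAR1 and shHuR inputs share the shControl input, so their ratios share its chance values. Across 13069 genes, which are not independent replicates, the correlation was 0.73 (Pearson) and 0.74 (Spearman), against a mean of 0.49 in simulated unchanged libraries. The covariance was 0.89 against a simulated 0.34, a difference of 0.55, and 78.7% of genes had the same sign against a simulated 66.2%. Both inputs had 686 genes higher and 1018 lower, against 111 and 227 for independent lists. The simulated unchanged libraries had means of 692 and 318. They kept the scaling factors of the real libraries, and scaling by total counts shifts the median ratio by -0.10 (shADAR1 input) and -0.03 (shHuR input). Those factors therefore raise the simulated ratios, which can add to the genes higher in both and take from those lower. The count of higher genes thus does not show whether their overlap exceeds chance. Part of the excess in covariance and in genes lower in both may come from the shared control library and cannot be split off with 1 control. With a control of its own, the RNA-seq knockdown had a correlation of 0.05 with the shHuR input (Spearman -0.03, covariance 0.05), with 216 genes higher in both and 183 lower, against 81.7 and 138 for independent lists.

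**Figure D2:**
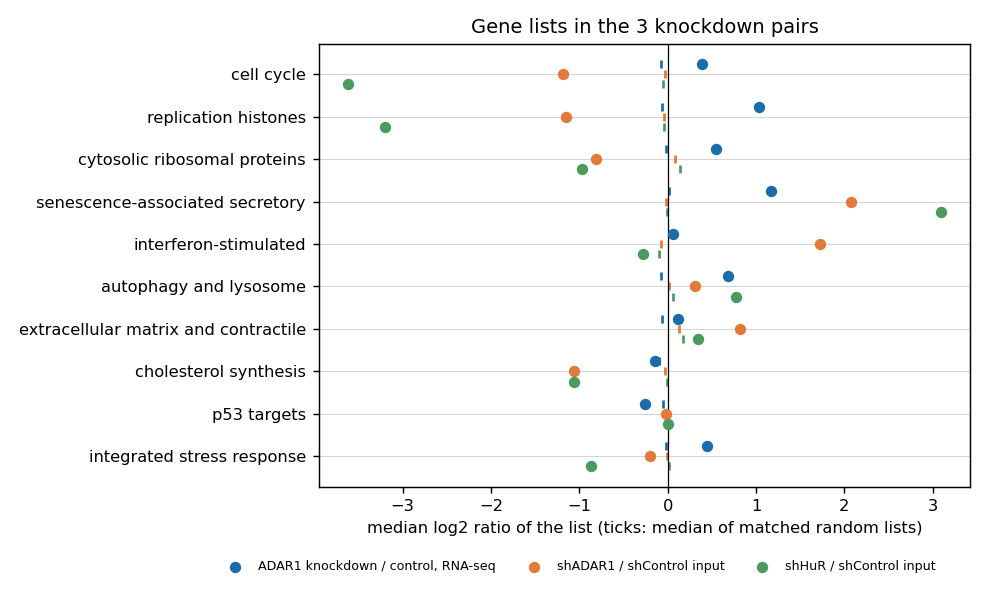
Median log2 ratio of each gene list (horizontal axis, circles; ticks for the median of matched random lists) in the RNA-seq knockdown, the shADAR1 input and the shHuR input against their controls, with 1 library per group. Cell cycle genes are at 0.38, -1.19 and -3.62, and senescence-associated secretory genes at 1.17, 2.08 and 3.09.

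In the HuR precipitate of shControl cells, HuR's own mRNA was above the input, and mRNAs of ribosomal proteins (median log2 -3.50 over 82 members, percentile 0) and histones (-3.12 over 30, percentile 0) were far below it. Reported HuR targets had 17 members enriched, 4 depleted and 7 neither of 28, and their median of 1.52 lay at percentile 83.9 among matched random lists, whose median was 0.99. AU-rich-element-binding proteins had 8 of 14 enriched and 0 depleted (median 1.30, percentile 56.6), so neither list stood apart from genes of like expression. ELAVL1 was enriched 9.99-fold (log2 3.32, interval 3.28 to 3.37), EIF4E, the cap-binding factor, 14.9-fold, ADAR 3.34-fold (1.74, 1.71 to 1.77), LMNB1 4.56-fold (2.19, 2.11 to 2.27) and SIRT1 2.36-fold (1.24, 1.12 to 1.35). CDKN2A lay below the input (-2.20, -2.46 to -1.95), and CDKN1A stood at -0.09 (-0.12 to -0.07). Of 13309 genes, 4090 were enriched at least 2-fold and 1703 of these were HuR-dependent. The 1703 were chosen for high shControl enrichment and then called on a drop from it. High values by chance in shControl and a general shift of the shHuR precipitate towards its input can therefore add to them. Among genes chosen on the mean of shControl and shHuR, rescaled enrichments took those lower in shHuR from 1097 to 672. Scaling by total counts lowered the median enrichment of all genes by 0.87 (shControl), 0.86 (shADAR1) and 0.99 (shHuR) on the log2 scale, so that 2383 genes were enriched in shControl and 963 HuR-dependent.

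The most enriched HuR-dependent genes by the fixed rule were, besides EIF4E, the ubiquitin-conjugating enzyme UBE2E2 (15.3-fold; interval 3.85 to 4.03 on the log2 scale), the homeobox repressor TGIF1 (14.0-fold), the fatty acid hydroxylase CYP4V2 (13.8-fold), TMED2, a cargo receptor of the secretory pathway (13.1-fold), and XKR9 (28.97-fold from 4 input counts; 3.43 to 6.77). PIRAT1 and IGF1 had 4 and 3 input counts, and AMIGO3, LUZP6 and IGF1 overlap other genes and are uncertain. For each of these the counting interval of the difference in shHuR included 0. Without rescaling, the log2 differences in shHuR were -1.07 for UBE2E2, -0.86 for EIF4E, -1.17 for TGIF1, -0.74 for CYP4V2, -1.16 for TMED2 and -1.99 for XKR9. A general shift of the shHuR precipitate towards its input would lower the most enriched genes most, so these calls alone do not show HuR dependence.

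Across the 3 lines, 4926 genes were enriched and 5087 depleted in the HuR precipitates in the edgeR test of 16232 genes. Leaving out the shADAR1 line gave 2831 enriched genes, and leaving out the line as block gave 3020 depleted genes. Of 29 reported HuR targets, 15 were enriched and 4 depleted (adjusted over the list alone, 15 and 4), among them ACTB (3.69, SE 0.23), EIF4E (3.41, SE 0.29) and the adhesion and signalling protein CTNNB1 (3.19, SE 0.25), each with an edgeR adjusted p of 1.05e-05 or 1.02e-05. Of 14 AU-rich-element-binding proteins, 8 were enriched and 0 depleted (adjusted over the list alone, 8 and 0), such as CELF1 (3.59, SE 0.26) and KHSRP (2.92, SE 0.26); 10 had an unadjusted p under 0.05. ELAVL1 was enriched at 2.61 (SE 0.37; edgeR adjusted p 0.00019), LMNB1 at 1.78 (SE 0.31; edgeR adjusted p 0.000684) and ADAR at 1.32 (SE 0.29; edgeR adjusted p 0.00255), and CDKN2A was depleted at -1.85 (SE 0.32; edgeR adjusted p 0.000643). SIRT1 was at 0.68 (SE 0.34, edgeR adjusted p 0.104) and CDKN1A at 0.00 (SE 0.24), neither past the threshold. The test counts the shHuR line, where HuR's own mRNA was lower, as a replicate. A loss of enrichment in that line lowers the mean and widens the spread. SIRT1 stood at 1.24, 0.69 and -0.06 in shControl, shADAR1 and shHuR, so its miss does not show a lack of recovery with HuR.

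Ribosomal protein mRNAs were depleted for 79 of 82 members and enriched for 0 (adjusted over the list alone, 81 and 0), with RPL12 at -3.71 (SE 0.35) and RPL39 at -3.56 (SE 0.32). Replication histones were depleted for 20 of 31 (adjusted over the list alone, 20) and enriched for 0, with H2AC21 at -3.79. Matrix and contractile mRNAs were depleted for 13 of 20 and enriched for 2 (adjusted over the list alone, 13 and 2), among them the contractile ACTA2 (-2.85) and TAGLN (-2.76) and fibronectin FN1 (-1.99). Interferon-stimulated genes were depleted for 17 and enriched for 6 of 29 (adjusted over the list alone, 17 and 6), from IFITM1 at -3.38 and ISG15 at -2.99 to IFIT5 at 2.98. Cell cycle genes were depleted for 17 and enriched for 3 of 30 (adjusted over the list alone, 17 and 3), with TK1 at -2.63, PLK1 at -2.55 and BIRC5, or survivin, at 2.82.

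Of 20 p53 targets, 7 were enriched and 6 depleted in the precipitates (adjusted over the list alone, 7 and 6), with TP53INP1 at 3.32, MDM2, a ubiquitin ligase, at 3.02 and ZMAT3 at 2.85. For 23 senescence-associated secretory genes the counts were 6 and 7 (adjusted over the list alone, 6 and 6), with IGFBP5 at 2.00 and MMP3 at -2.49. The stress response had 2 enriched and 9 depleted of 14 (adjusted over the list alone, 2 and 10), with ASNS at -2.65 and ATF4 at -2.24. Autophagy and lysosome genes had 2 and 10 of 18, cholesterol synthesis 1 and 6 of 12, and sirtuins 1 and 4 of 7, each as many when adjusted over the list alone, with the lysosomal protease CTSD at -2.48, FDPS at -2.55, SIRT2 at -2.46, and SIRT5 enriched. Of the RNA editing enzymes ADAR was enriched and ADARB1 (0.31, SE 0.38) did not pass. Among markers of other cell types, EPCAM (-3.16), TEK (-1.30), CD68 (-1.87) and CD14 (-2.64) were depleted and LYZ, or lysozyme, was enriched at 2.57.

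**Figure D3:**
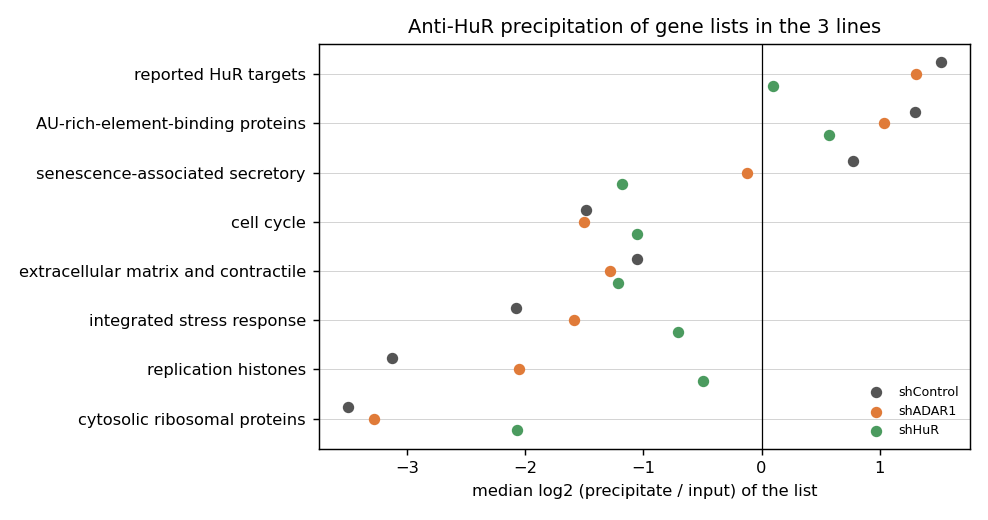
Median log2 ratio of HuR precipitate to input for each gene list (horizontal axis) in shControl, shADAR1 and shHuR cells, with 1 library pair per line. Reported HuR targets are at 1.52, 1.30 and 0.09, where the last is -0.89 with scaling by total counts, and ribosomal proteins at -3.50, -3.28 and -2.06.

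SIRT1 was 1.46-fold less enriched in the HuR precipitate of shADAR1 cells than in that of shControl cells (log2 difference -0.55, interval -0.76 to -0.34), short of the 1.5-fold limit, with 1.61-fold enrichment in shADAR1 (0.69, 0.51 to 0.87; -0.17 with scaling by total counts). ELAVL1 stood at -0.39 (-0.46 to -0.33), LMNB1 at -0.40 (-0.57 to -0.24), ADAR at -0.25 (-0.32 to -0.18), CDKN1A at 0.23 (0.19 to 0.26) and CDKN2A at 0.23 (-0.10 to 0.56). Of the 4159 genes enriched over both lines, 642 were lower and 503 higher in shADAR1, their median difference was -0.16, and 17.6% had a value below that of SIRT1, which is not of this set, since its mean log2 enrichment was under 1. With the shADAR1 enrichments rescaled to the spread of shControl, 332 genes were lower and 894 higher, so that 72.9% of the called genes were higher in place of 43.9%. SIRT1 then stood at -0.44 (-0.66 to -0.22) and LMNB1 at -0.19 (-0.37 to -0.01), and the intervals of ADAR and ELAVL1 (-0.07 each) included 0.

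Lower in shADAR1 among the enriched genes were the stress ligand ULBP1 (4.14-fold; log2 interval -2.54 to -1.56), CADPS2 (3.51-fold) and EFHC2 (3.36-fold), and higher were NDRG2 (9.67-fold, at the lower bound 3.74-fold) and the netrin NTN3 (6.91-fold; 1.11 to 4.47). PCDHGC5 was 28.4-fold higher (log2 interval 0.70 to 8.95). The antisense gene EPB41L1-AS1 (7.50-fold higher) is uncertain. So are INMT-MINDY4, NPIPB13, AMIGO3, PHLDA1-AS1 and PTGES3L-AARSD1, which overlap others or belong to families. The intervals of DOK5, DKK2, ATP8B4, RIOX1, SLC52A1 and PTGES3L-AARSD1 included 0. Senescence-associated secretory genes were less enriched in shADAR1, with a median of -0.74 over 19 members (-0.66 without a member at 0 counts; percentile 0), 11 lower and 2 higher, among them CXCL8 (3.48-fold lower) and CCL2 (2.23-fold lower). Reported HuR targets had 6 lower and 1 higher of 29 (median -0.19, percentile 27.7), such as the cytokine IL6 (2.16-fold), the chromatin protein PTMA (2.08-fold) and HIF1A (2.06-fold lower). Replication histones, with 24 higher and 2 lower of 30 (median 0.81, or 0.79 without a member at 0 counts), lay at percentile 100. The input enters abundance and enrichment differences with opposite sign, and random lists were not matched on it. Secretory genes and histones had medians of 2.08 and -1.15 in the shADAR1 input, opposite to their enrichment differences. Cell cycle genes, at -1.19 in that input, had an enrichment difference of -0.06. CXCL8 had 53 precipitate and 26 input counts in shControl. These list values alone therefore do not show a change in binding to HuR. Matrix and contractile genes had 4 lower and 2 higher of 19 (median -0.06, percentile 71.4), with the proteoglycans LUM (2.71-fold) and DCN (2.25-fold) among the lower.

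In the shHuR precipitate, enrichment of HuR's own mRNA was 2.62-fold (log2 1.39, interval 1.24 to 1.54), a log2 difference of -1.93 (-2.09 to -1.77) from shControl. SIRT1 was 2.45-fold less enriched (-1.29, -1.55 to -1.03) and stood at -0.06 (-0.30 to 0.18) in shHuR itself. ADAR had a difference of -1.17 (-1.22 to -1.11), with an enrichment of 0.57 in shHuR that turned to -0.43 with scaling by total counts. LMNB1 had a difference of -1.08 (-1.60 to -0.57) and CDKN2A of 0.64 (0.33 to 0.95). Of the 3813 genes enriched over both lines, 1097 were lower and 955 higher in shHuR, and 9.34% had a value below that of SIRT1, again not of the set. With rescaled enrichments, 672 were lower and 1979 higher (74.7% higher in place of 46.5%), and among genes enriched in shControl alone 1752 were lower (30.5% higher). The rescaled differences in shHuR were -0.94 for ADAR, -1.51 for ELAVL1, -1.22 for SIRT1 and -0.73 for LMNB1 (counting interval -1.38 to -0.09).

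The histone deacetylase HDAC2 (8.51-fold; -3.20 to -2.98), the chemokine CCL2 (7.78-fold), the transcription activator CAMTA1 (7.07-fold), the channel TMCO1 (6.06-fold), and the RNAs DUXAP8 (9.77-fold) and ESRG (10.95-fold) were less enriched in shHuR than in shControl. ATP8B4 was 6.43-fold less enriched (log2 interval -5.07 to -0.30), and the intervals of DKK2, AMIGO3 and LUZP6, ranked among the lower genes, included 0. More enriched were STAP2 (25.7-fold, log2 interval 3.06 to 6.30), NEB (19.1-fold, 1.49 to 7.03), ZNF835 (16.2-fold, 1.14 to 6.90) and NDRG2 (11.5-fold). So were TMEM202-AS1 (10.1-fold), KCNJ11 (9.70-fold) and DENND6B (9.36-fold). TGIF2-RAB5IF, a readthrough gene, and NBPF20, of a multigene family, are uncertain, and the interval of C10orf67 included 0. Reported HuR targets had 11 lower and 2 higher of 29 (median -0.29, percentile 7.88), with CXCL8 7.36-fold, HIF1A 5.42-fold and PTMA 5.12-fold lower; their median enrichment was 1.52, 1.30 and 0.09 in shControl, shADAR1 and shHuR, and the last was -0.89 with scaling by total counts. AU-rich-element-binding proteins had 7 lower and 1 higher of 14 (median -0.61, percentile 3.40), with IGF2BP3 3.52-fold and ZFP36L1 3.34-fold lower, and secretory genes 15 lower and 5 higher of 23 (median -1.49; -1.44 without members at 0 counts; percentile 0). Ribosomal proteins had 63 higher and 2 lower of 82 (median 1.29; 1.31 without a member at 0 counts; percentile 100) and histones 28 higher and 1 lower of 30 (median 2.43; 2.34 without a member at 0 counts), with H2AC11 24.4-fold higher. Secretory genes, ribosomal proteins and histones had medians of 3.09, -0.97 and -3.19 in the shHuR input, opposite to their enrichment differences. Cell cycle genes, at -3.62 in that input, had an enrichment difference of 0.30. These list values share the input, so they alone do not show a change in binding to HuR. The differences of shADAR1 and shHuR against shControl had a correlation of 0.73 across 13592 genes (Spearman 0.75), against 0.50 in simulated unchanged libraries, and a covariance of 0.67 against a simulated 0.46, a difference of 0.21, with 76.8% of genes of the same sign against 66.3%. Part of that excess may come from the shared shControl libraries.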

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

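Of the tests in this part, those of swapped labels, of the state of the cultures, of the likeness of both inputs of the ribosomal protein contraction and of SIRT1 in shHuR were chosen after the results were seen, and so were the spread between libraries as bound for SIRT1, the removal of GC and length trends and the rescaling of enrichments as settings.

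Cell cycle genes had a median log2 ratio of 0.38 in the RNA-seq knockdown and of -1.19 in the shADAR1 input, so the same knockdown went with opposite directions in 2 experiments; the difference was not tested, since each experiment held 1 library per group. The same reason singles out the ribosomal proteins (medians 0.55 and -0.81), the replication histones (1.03 and -1.15) and LMNB1 (log2 ratios 0.54 and -1.29), for which the difference was not tested either. Trends over GC content and transcript length ran opposite ways in the 2 experiments. Spearman correlations with GC content and length were 0.38 and -0.33 in the RNA-seq and -0.30 and 0.21 in the shADAR1 input. With these trends removed from both pairs, the cell cycle medians still lay 1.44 apart. That argues against such a bias as the whole cause for the cell cycle genes. For the ribosomal proteins, histones and LMNB1 such a bias stays open. A swap of control and knockdown labels in one experiment is excluded by ADAR, whose log2 ratio nearest to 0 was -1.56 in the libraries labelled as knockdown. A different state of the cultures, such as passage or time after knockdown, may account for it, and 0 further libraries at other times or passages were at hand to test it, so it cannot be told apart from other differences between the experiments.

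The shADAR1 and shHuR inputs differed alike from the shControl input. Chance values of the shared control do not account for all of it. The covariance of 0.89 lies above the highest of the simulated unchanged libraries, 0.35 (dispersion 0.150, from the fit of both ADAR1 knockdown experiments). The count of 1018 genes lower in both also lies above the highest simulated count, 343. By contrast, the 686 genes higher in both lie under the highest simulated count, 731. The simulation kept the scaling factors of the real libraries, which shift its ratios upwards. That can raise the simulated count of higher genes and lower that of lower genes. The dispersion used also holds the differences between the 2 experiments, so it may overstate the chance spread of 1 input. The simulation therefore cannot decide for the genes higher in both, and for these chance stays open. A candidate explanation is a real state of the shControl culture that both comparisons carry. With a control of its own, the RNA-seq knockdown had a covariance with the shHuR input that was 0.056 times that of the shADAR1 input, as that explanation needs. RNA-seq cultures that differed from the input cultures for any other reason would give this value too, so an effect that both knockdowns share stays open.

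In the precipitate of shHuR cells 11 of 29 reported HuR targets were lower and 2 higher in enrichment (median -0.29, percentile 7.88), and SIRT1 was lower there and, short of the 1.5-fold limit, in that of shADAR1 cells. In shHuR the ribosomal protein mRNAs, which the shControl precipitate held little of, had 0.59 times the log2 depletion of shControl. A general contraction of the precipitate towards its input, as less HuR or more unspecific RNA could give, would have this effect. In shADAR1 their median was -3.28, against -3.50 in shControl and -2.06 in shHuR, so by this measure contraction was small in shADAR1. After rescaling to the spread of shControl, the reported HuR targets had a median difference of -0.04 in shHuR, with 9 of the 11 lower members still lower and those higher going from 2 to 7, while AU-rich-element-binding proteins kept -0.38, from -0.61, with all 7 lower members still lower and those higher going from 1 to 3. SIRT1 was then at -1.22 in shHuR (counting interval -1.53 to -0.91), from -1.29, so rescaling took away little of the measured difference, and at -0.44 in shADAR1 (-0.66 to -0.22), from -0.55. The bound set before for SIRT1 in shADAR1, a counting interval that excludes 0, was wrong, since it leaves out the spread between single libraries. With the dispersion of 0.1004 from the precipitation test, the intervals run from -3.27 to 0.82 in shHuR and from -2.34 to 1.45 in shADAR1. That dispersion also holds the differences in enrichment between the lines, so these intervals may be wider than chance alone would give. Even ELAVL1 in shHuR, at -1.51 after rescaling, has such an interval from -3.54 to 0.52. This bound therefore cannot decide the question. For SIRT1, contraction together with chance between libraries cannot be told apart from a loss of binding in either line.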

How the results depend on the processing

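Removal of the GC and length trends and the rescaling of enrichments were chosen after seeing the data; the other settings were planned. The cause was not tested for any value in this part, except that a higher minimum count leaves fewer genes by construction. A minimum of 200 counts gave 672 genes higher in the RNA-seq knockdown, 100 higher and 76 lower in both experiments, and 265 and 615 with higher enrichment in shADAR1 and in shHuR. With log2(FPKM + 1), 621 genes were higher and 570 lower in the RNA-seq knockdown, and 100 higher and 69 lower in both experiments. Scaling by total counts gave 2383 enriched genes in shControl, 963 HuR-dependent, 329 lower and 315 higher in shADAR1, and 486 lower and 580 higher in shHuR. Among genes enriched in shControl alone, 1752 were lower in shHuR. Rescaled enrichments gave 332 lower and 894 higher in shADAR1, and 672 lower and 1979 higher in shHuR. With trends over GC content and length removed, 619 genes were lower in the RNA-seq knockdown, and the other 7 counts tried stayed within 1.5 times.

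For ADAR1 knockdown over both experiments, DESeq2 gave 92 genes up and 24 down, and no filter on low counts gave 140 and 34. Without the experiment as replicate block, edgeR gave 0 up and 0 down, with 85 genes at an unadjusted p under 0.05. For HuR precipitate against input, the fit with no replicate block gave 3590 genes up and 3020 down; the line is the block there, and the count up stayed within 1.5 times. Leaving out one line gave 2831 (without shADAR1) to 5383 genes up and 3589 (without shADAR1) to 5863 down.

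Of all 98 counts tried under an alternative, 69 stayed within 1.5 times and 29 moved. The side with more calls turned for the RNA-seq knockdown at a minimum of 200 counts (672 higher and 788 lower, from 1100 and 1020), for the shADAR1 input with GC and length trends removed (1259 higher and 954 lower, from 1179 and 1395), for shADAR1 with rescaled enrichments, and for shHuR with rescaled enrichments, with total counts and at a minimum of 20 counts (1271 higher and 1237 lower). For HuR precipitate against input, 4926 up and 5087 down, it turned with DESeq2 (5172 and 5147), DESeq2 size factors (5055 and 5031), no replicate block, and without shControl (4346 and 4084). Of the medians of lists, 254 stayed within the order-statistic interval of the median over its members and 28 moved, and of the ratios of target genes 70 stayed and 44 moved, 24 of these with scaling by total counts. That scaling shifted the median of all genes by -0.10 in the shADAR1 input and -0.12 in the shHuR enrichment difference, and DESeq2 size factors shifted it by 0.11 in the shADAR1 enrichment and -0.11 in the shHuR difference. Medians turned sign with total counts for secretory genes in shControl (0.77 to -0.10), AU-rich-element-binding proteins in shHuR (0.57 to -0.43), and the interferon-stimulated (0.08 to -0.08) and cholesterol synthesis genes (0.10 to -0.02) in the shHuR difference. FPKM values were not used here for the precipitation experiment, so that alternative was not run there. Genes with few counts have wide intervals: CFTR, with 1 control count, has a log2 interval from 4.11 to 11.93.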

Other observations

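Other splits of the libraries, the ribosomal protein value, the GC classes for the loss of enrichment in shHuR and the removal of GC and length trends as a setting were chosen after results were seen; the other tests in this part were written down before their results.

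Some mRNAs were far above the input in the HuR precipitate of shHuR cells as well as in that of shControl cells. ACTB had a log2 enrichment of 3.52 in shHuR and of 3.81 in shControl. CELF1, which binds GU-rich elements, was at 3.59 and 3.47, the p53 target TP53INP1 at 3.22 and 3.43, and MDM2 at 2.94 and 3.08. BIRC5 was at 2.95 in shHuR (2.62 to 3.29), although its input level was 29.6-fold lower there. These values hold 1 library pair per line, and scaling by total counts lowers the median enrichment in shHuR by 0.99.

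Of the sirtuins, SIRT1 was the member with lower enrichment in shHuR, and SIRT7 (log2 difference 2.74, interval 2.08 to 3.40), SIRT2 (1.83, 1.53 to 2.14) and SIRT6 (1.79, 1.36 to 2.23) were higher. In shADAR1, SIRT7 (1.56, 0.83 to 2.30) and SIRT2 (0.86, 0.54 to 1.18) were higher as well. Over the 3 lines, the edgeR log2 ratios of precipitate to input were -2.46 for SIRT2, -2.01 for SIRT6 and -1.70 for SIRT7. These mRNAs were depleted, so higher here means less depleted. In the RNA-seq knockdown, SIRT6 stood at 0.87 (0.55 to 1.19), SIRT2 at 0.72 (0.58 to 0.85) and SIRT3 at -0.78 (-1.17 to -0.39).

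The first hypothesis was that AU-rich 3' UTRs may go with HuR precipitation, since HuR binds AU-rich elements. Across genes, which are not independent replicates, the lowest Spearman correlation of shControl enrichment with the AU content of the 3' UTR was 0.35 among 3 classes of 3' UTR length of equal size. Among 5 classes of GC content outside the 3' UTR it was -0.15, 0.11, 0.26, 0.40 and 0.46 from the lowest class to the highest, so 4 of 5 classes kept the direction and the lowest turned it, and the GC content of the rest of the transcript stays open for part of the relation. The loss of enrichment in shHuR went with AU content in each length class, with -0.55 the value nearest to 0, consistent with the hypothesis; for the classes of GC content, from -0.11 to -0.50, no bound was written down. A general contraction of the shHuR precipitate, to which the ribosomal protein value of 0.59 pointed, may add to it.

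The second hypothesis was that mRNAs bound by HuR may be less abundant after ADAR1 knockdown. In the RNA-seq, 1583 HuR-dependent enriched genes had a median log2 ratio of -0.29, at percentile 0 of matched random lists, whose median was -0.04. With the trends over GC content and length removed, the median was 0.03 for 1561 genes, at percentile 18.5, so a GC or length bias between the libraries is a candidate explanation and the hypothesis stays undecided. In the shHuR input, 3498 genes enriched in the shADAR1 precipitate had a median of 0.09, at percentile 100, and 1601 of them lay below 0. With the trends removed the median was 0.08 for 3375 genes, at percentile 74.4. Both values lay on the side written down beforehand as against lower abundance. The second lies within the range of the random lists (0.04 to 0.10), so it shows no difference from genes of like expression. Without a mock precipitate the set may hold unspecifically recovered mRNAs. Lower abundance of enriched mRNAs was thus not seen in shHuR cells, and for bound mRNAs the question stays open.

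The 6 libraries of the precipitation experiment allow 10 splits into groups of 3, too few for a share under 0.05. The real split, 1 of 10, called 10013 genes in edgeR and the highest of the others 0, with at most 233 genes at an unadjusted p under 0.05. The real split and 3 of the others part all 3 pairs of precipitate and input, and those others also mix precipitates and inputs within a group.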
